A study of Homo sapiens with 12 samples.

How the data were processed

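Per the labels' protocols, polysomes of HCT116, MCF7 and SJSA cells were separated on sucrose gradients, their RNA was extracted with phenol and chloroform, selected for polyA and made into Ion Torrent libraries. The deposited table holds whole-number read counts per gene symbol, not normalized, which the authors made with HTSeq 0.6.1 in intersection-nonempty mode, per the labels. The submitters' processing notes also name GSNAP, FastQC 0.11.2, SAMtools 0.1.19, Picard 1.129, deepTools 2.2.2 and the genome build hg19, without their roles. The annotation and the strand setting of the counting were not given in the sources used here. Without a known strand setting, reads of antisense and overlapping genes cannot be told from those of their partners, and reads of near-identical paralogs or pseudogenes (LCE1 genes, ribosomal protein genes) can be lost or misplaced, so such genes are uncertain. PolyA selection leaves out most RNA without a polyA tail, and no coordinates are printed because the reference used here for gene properties, GRCh38 with GENCODE v29, is of another build. The table names no mitochondrially encoded genes.

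The labels give 12 libraries in 6 groups of 2, by line and treatment, with a batch number each. They do not say that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. Counts summed to 49283068 and 37580120 in HCT116 DMSO 1 and 2 and to 47842600 and 41266663 in HCT116 Nutlin. They summed to 32473932 and 34952177 in MCF7 DMSO and 54596326 and 51281355 in MCF7 Nutlin, and to 50716283 and 49782541 in SJSA DMSO and 51282703 and 36492652 in SJSA Nutlin. The 10 most counted genes took between 3.41% and 9.96% of a library. Replicates of a group were not copies of each other (chi-square per degree of freedom from 90.5 to 242 against counting noise), which does not show that they are independent.

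Of 25369 genes, 2758 had no count and 17005 passed the edgeR filter filterByExpr for the 6 groups (minimum count 10, minimum total 15). All 12 libraries entered 1 edgeR 4.0.16 quasi-likelihood fit (glmQLFit with robust, glmQLFTest) in R 4.3.3, with a mean per group and TMM scaling, whose factors were 0.752 and 0.748 in SJSA Nutlin, 0.961 and 0.857 in SJSA DMSO and between 0.981 and 1.22 elsewhere. The common biological coefficient of variation was 25.3%, with 6 residual degrees of freedom. Contrasts were Nutlin against DMSO in each line, their average over the lines, a joint F-test of the interaction, the interactions of each pair of lines, and the lines under DMSO. Adjusted p-values are Benjamini-Hochberg over all tested genes at a threshold of 0.05. The SE of a log2 fold change was taken as its size divided by the square root of F. CPM used the scaled library sizes. Where a group had 0 counts, the fold is a lower bound against 3 counts over the group, and with 1 to 3 counts it is the ratio of scaled counts with an exact 95% interval. Such intervals and floors cover counting error only.

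Before the data were examined, 25 gene lists were written from general knowledge: p53 targets of arrest and feedback, apoptosis, DNA repair, metabolism and redox, autophagy and lysosome, and secreted and surface products, then G1/S and DNA replication, G2/M and mitosis, cytosolic ribosomal proteins, other TOP mRNAs of translation, ribosome biogenesis, sterol synthesis, integrated stress response, hypoxia and glycolysis, interferon response, NF-κB and inflammatory, MAPK and immediate early, estrogen response, epithelial, mesenchymal and bone, luminal breast and intestinal identity, snoRNA host genes, nuclear noncoding RNAs, and mitochondrially encoded mRNAs. The last had no member in the table, so 24 were tested. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with an estimated correlation and with fry beside it, and adjusted over the lists of a contrast. Of the 24 lists 12 passed in HCT116, 15 in MCF7 and 13 in SJSA, and 7, 7 and 2 also with an estimated correlation. Fry, which tests whether a list's genes move one way on balance and not against other genes, passed 9, 12 and 11. Members were also counted with p-values adjusted over the list alone.

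Genes were named by a rule also written then. In each line CDKN1A, MDM2, TP53, BBC3, GDF15 and SESN1 were always named, then the 8 largest rises and 8 largest falls among called genes with a mean of at least 50 counts in the line and the same direction in both batches, then up to 4 called members of each list by p. Over the lines the rule took the 10 shared rises and 10 shared falls largest in mean, and the 12 genes with the smallest p for the interaction. Some list members chosen by the rule are covered in the counts only.

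Batch numbers pair the samples of a line, since the labels give them as batches. Deviations from the group mean correlated between same-numbered libraries at 0.17 in HCT116, 0.41 in MCF7 and 0.2 in SJSA. Between libraries of different lines such correlations ran from −0.14 to 0.18. The HCT116 value lay within that range, the SJSA value just above it and only the MCF7 value well above it. The fit above has no block, and a fit with the batch number within each line as a block (3 residual degrees of freedom) is given beside a result where it changed it. Other alternatives were DESeq2 1.42.0 size factors and upper-quartile scaling, no filter and a filter of 50 counts in 2 libraries, DESeq2, limma-voom, fits of the compared lines alone, libraries thinned to the smallest total, and each library left out in turn, where the lone sample of a group is assumed to vary like the other groups. After the data were seen, a spline trend (5 degrees of freedom) of each library on transcript GC content and length was removed within lines, without and with the block, for the 16374 tested genes (96.3%) with both values. Gene symbols were matched to the reference for 22679 genes directly and for 921 through older symbols, and 1769 were not matched.

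The test was tried on simulated counts with 200 changed genes among 16680, made from the means and depths of these libraries. It recovered 22%, 25% and 29% of 100 genes changed 2-fold in HCT116, MCF7 and SJSA, and 92%, 93% and 97% of 100 changed 4-fold. So 2-fold changes were mostly missed in these simulated counts, with 200 changed genes per line. The adjusted threshold is easier to pass where more genes change. These shares therefore do not carry over as they stand to the real data, where 4.58%, 7.12% and 27.1% of tested genes were called in HCT116, MCF7 and SJSA. Of 127, 128 and 141 calls in these lines, 13, 10 and 15 were false, or 10.2%, 7.81% and 10.6%. Each share was above the threshold of 0.05, so the test exceeded its stated error rate in these simulated counts. In simulated SJSA data of 16093 genes with a GC trend but no change, 1288 genes were called, and 0 once the trend was removed. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.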

Results

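Polysome-associated polyadenylated RNA was sequenced from 3 human cancer cell lines treated for 12 h with 10 µM Nutlin or with 0.2% DMSO. HCT116 is a colorectal adenocarcinoma line, MCF7 a breast carcinoma line and SJSA an osteosarcoma line, and all carry wild-type TP53. Nutlin is a small molecule that occupies the p53-binding pocket of MDM2, the ubiquitin ligase that keeps p53 low, and so activates p53. Polysomes are mRNAs that carry several ribosomes, so a value here reflects both how much of an mRNA was present and how much of it was on polysomes. Total RNA was not analysed here. Each of the 6 groups held 2 libraries, from batch 1 and batch 2. Gene counts summed to between 32473932 and 54596326 per library, and 17005 of the 25369 genes in the table were tested. Within a group, log2 expression correlated between 0.981 and 0.989 across genes, which are not independent replicates. The first principal components separated the lines (51.9% and 34.9% of the variance), and component 3 (5.58%) separated Nutlin from DMSO in every line. Values are CPM, scaled by library size, with SD and n = 2 libraries, or log2 fold changes of Nutlin against DMSO ± SE. Adjusted p-values come from the edgeR quasi-likelihood test.

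The comparison within HCT116 asked which mRNAs changed on polysomes when p53 was activated in a colorectal line. CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, rose from 238 ± 39.5 to 2778 ± 283 CPM (log2 fold change 3.54 ± 0.36, adjusted p = 7.57e-06). MDM2, itself a p53 target, rose from 82.0 ± 3.54 to 536 ± 99.3 CPM (2.71 ± 0.31, adjusted p = 1.81e-05). Genes of DNA replication and of mitosis fell together, with a median log2 fold change of −2.18 over 41 G1/S and replication genes and of −2.04 over 40 G2/M genes. BBC3, which encodes the BH3-only protein PUMA, rose from 25.7 ± 0.432 to 114 ± 11.4 CPM (2.14 ± 0.30, adjusted p = 9.89e-05), SESN1 rose by 2.36 ± 0.28 on the log2 scale (adjusted p = 3e-05) and the cytokine gene GDF15 by 2.17 ± 0.44 (adjusted p = 0.00442). For these 5 genes, both Nutlin libraries lay above both DMSO libraries. TP53 itself stood at 102 ± 27.1 CPM with DMSO and 71.6 ± 3.87 with Nutlin and did not pass the test (−0.51 ± 0.31, adjusted p = 0.414).

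**Figure D1:**
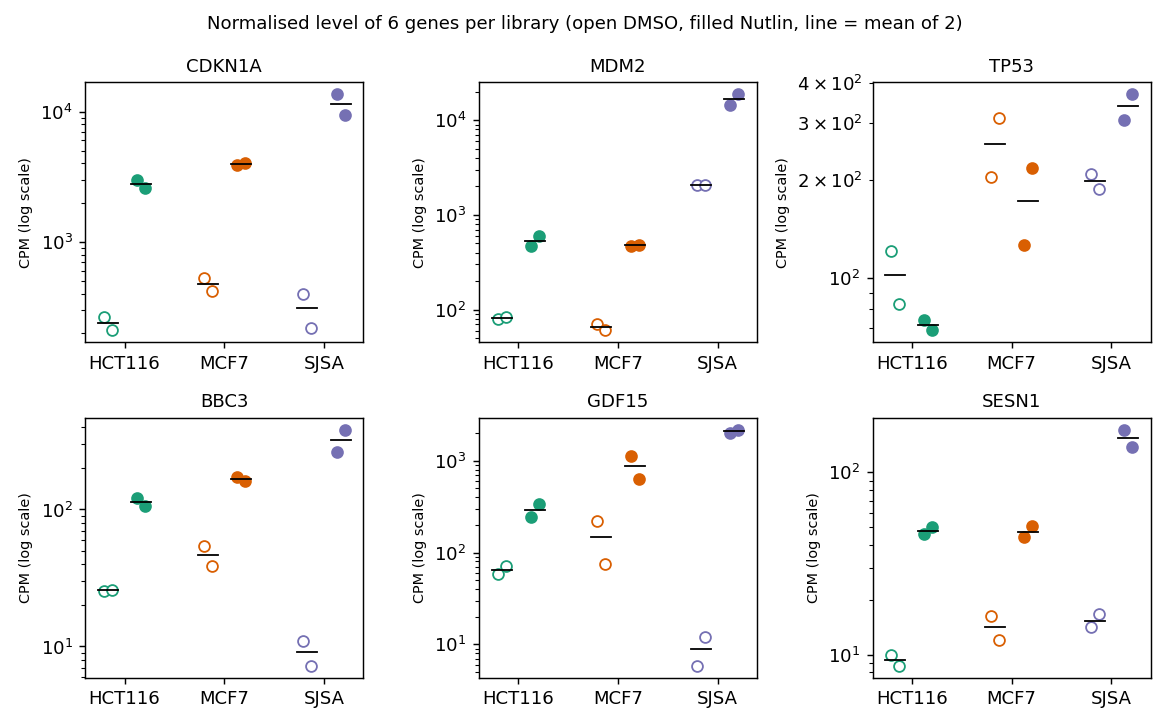
CPM on a log axis of CDKN1A, MDM2, TP53, BBC3, GDF15 and SESN1 in each library of HCT116, MCF7 and SJSA, with open circles for DMSO, filled circles for Nutlin and a line at the mean of the 2 libraries. In SJSA, GDF15 went from 8.93 to 2104 CPM, and MDM2 under DMSO was already at 2088 CPM against 82.0 in HCT116 and 65.7 in MCF7.

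In HCT116, 9 of the 12 p53 arrest and feedback targets rose (12 adjusted over the list alone), with a median log2 fold change of 1.53 and a camera adjusted p of 9.86e-19. They included BTG2 (3.0 ± 0.37, adjusted p = 3.01e-05), an antiproliferative gene, and ZMAT3 (2.33 ± 0.30). Of 20 p53 apoptosis targets 10 rose (10 adjusted over the list alone, camera adjusted p = 2.27e-13), among them TP53INP1 (3.74 ± 0.30), TP53I3 (3.84 ± 0.36) and the death receptor gene FAS (2.56 ± 0.34). Of 10 p53 DNA repair targets 6 rose and 1 fell (8 and 1 adjusted over the list alone). Camera gave the list an adjusted p of 1.24e-05. Those that rose included RPS27L (2.42 ± 0.35) and the ribonucleotide reductase subunit gene RRM2B (1.97 ± 0.33), and the Fanconi anaemia gene FANCC (−1.11 ± 0.30, adjusted p = 0.0371) fell. Of 16 metabolism and redox targets 7 rose (10 adjusted over the list alone, camera adjusted p = 4.58e-08), among them FDXR (1.98 ± 0.30), which encodes ferredoxin reductase. Of 20 secreted and surface targets 11 rose (13 adjusted over the list alone, camera adjusted p = 5.94e-11), among them SULF2 (2.91 ± 0.36), CD82 (2.04 ± 0.29) and INPP5D (4.53 ± 0.64), a list member although its product is intracellular. Of 11 autophagy and lysosome targets DRAM1 (2.02 ± 0.29, adjusted p = 0.00014) rose (4 adjusted over the list alone, 4 with the batch number as a block), with a camera adjusted p of 0.077. The G1/S list had 37 of 41 genes lower (39 adjusted over the list alone, camera adjusted p = 2.59e-60), for example the cyclin gene CCNE2 (−3.11 ± 0.36), the replicative helicase gene MCM2 (−2.55 ± 0.29) and EXO1 (−3.11 ± 0.36). The G2/M list had 39 of 40 lower (40 adjusted over the list alone, camera adjusted p = 3.96e-56), among them MKI67 (−2.31 ± 0.29). The camera calls of these lists other than the autophagy list held with an estimated correlation (adjusted p from 0.00326 to 0.0472).

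Among other lists in HCT116, sterol synthesis had 3 of 25 genes lower and 1 higher (8 and 1 adjusted over the list alone, 11 and 1 with the batch block). The 3 were INSIG1 (−1.73 ± 0.30), DHCR24 (−1.36 ± 0.32) and ACAT2 (−1.40 ± 0.37), and the 1 was TM7SF2 (1.15 ± 0.32). The list's median was −0.71 and its camera adjusted p was 1.56e-06, or adjusted p = 0.402 with an estimated correlation. Of 39 ribosome biogenesis genes TCOF1 (−1.13 ± 0.31) fell (4 adjusted over the list alone, 5 with the block). The list had a camera adjusted p of 2.3e-05, and the adjusted p was 0.444 with an estimated correlation. Of 17 NF-κB and inflammatory genes ICAM1 (2.70 ± 0.43), CXCL8 (1.72 ± 0.46) and IL1A (31 counts with Nutlin against 0 with DMSO, at least 9.23-fold higher) rose (6 adjusted over the list alone, 5 with the block). As a set it had a camera adjusted p of 0.00096, and the adjusted p was 0.177 with an estimated correlation. Of 27 interferon response genes TRIM22 (2.95 ± 0.66) and TLR3 (2.29 ± 0.52) rose and OAS3 (−1.52 ± 0.31) fell (2 and 1 adjusted over the list alone). The set test with camera gave an adjusted p of 0.624. Of 25 integrated stress response genes NUPR1 (3.33 ± 0.59) and ATF3 (1.52 ± 0.30) rose (3 higher and 2 lower adjusted over the list alone, 4 and 3 with the block). That list's median was −0.10, its mean 0.07 and its camera direction downward (adjusted p = 0.629). Of the estrogen response list MYB (−2.45 ± 0.44) fell (1 of 17, and 1 adjusted over the list alone). For the whole list camera gave an adjusted p of 0.451. Of the mesenchymal and bone list COL5A1 (3.63 ± 0.47) rose and TGFBI (1 count with Nutlin against 15 with DMSO, higher with DMSO by a ratio of 16.8, 95% interval 2.58 to 707) fell (1 and 1 of 16, also adjusted over the list alone). The list's adjusted p by camera was 0.629.

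No member was called in HCT116 by edgeR for 79 ribosomal protein genes (1 at an unadjusted p below 0.05, camera adjusted p = 0.418), 19 other TOP mRNAs (2, 0.629), 20 hypoxia and glycolysis genes (5, 0.0407), 19 MAPK and immediate early genes (3, 0.782), 14 epithelial genes (3, 0.0761), 11 luminal genes (2, 0.223), 8 intestinal genes (0, 0.779), 12 snoRNA host genes (4, 0.00271) or 5 nuclear noncoding RNAs (2, 0.629). DESeq2 called 1 member each of the epithelial, luminal and snoRNA host lists, limma-voom 1 of the snoRNA hosts, and neither called any other member of these lists. Adjusted over the list alone, 1 luminal gene was lower and no other member passed. With an estimated correlation the hypoxia list had an adjusted p of 0.371 and the snoRNA hosts 0.506. With the batch block 4 hypoxia genes were lower, 4 snoRNA hosts higher, 1 MAPK gene and 1 other TOP mRNA higher and 1 of each lower, and 1 epithelial, 1 luminal and 1 noncoding RNA gene lower, and the epithelial list had a camera adjusted p of 0.033. With 1 library left out, the camera call of the hypoxia list ended (0.0646 without HCT116 DMSO 1, 0.0549 without Nutlin 1, 0.06 without Nutlin 2), as did that of the snoRNA hosts (0.659 without DMSO 1, 0.126 without Nutlin 2). The autophagy list (0.0167 without DMSO 1), the epithelial list (0.0253 without Nutlin 2, 0.0466 without DMSO 2), the estrogen list (0.021 without DMSO 2) and the luminal list (0.000848 without DMSO 2) passed. The median of the nuclear noncoding RNAs was 0.30, their mean 0.13 and the camera direction downward.

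In all, 778 genes passed in HCT116, 332 higher and 446 lower, and 763 of them by more than 2-fold (1791 with the batch number as a block, 777 of the 778 kept). Fitted alone, HCT116 had 1920 genes, and the balance turned to 630 higher and 540 lower with no filter, 899 and 892 with the block, and 247 and 235 without HCT116 Nutlin 2. The 8 largest rises with enough counts were ABCA12 (4.93 ± 0.46), SORCS2 (4.83 ± 0.50), KLHL30 (4.55 ± 0.55), INPP5D, CBS (4.30 ± 0.66), PVRL4 (4.29 ± 0.45), now named NECTIN4, PTCHD4 (3.99 ± 0.47) and TP53I3. Several started near 0, such as CBS, at 0.07 and 0.12 CPM with DMSO and 3.07 and 0.68 with Nutlin. The 8 largest falls ran from ZNF367 (−3.25 ± 0.36), WDR76 (−3.25 ± 0.35), CCNE2, EXO1 and CLSPN (−3.05 ± 0.41), which encodes the checkpoint adaptor claspin, to DTL (−3.01 ± 0.33), KCNJ2 (−2.91 ± 0.62) and FAM111B (−2.79 ± 0.41). The count was 341 without HCT116 DMSO 1, 333 without Nutlin 1 and 482 without Nutlin 2. Leaving out at least 1 HCT116 library ended the calls of GDF15 (0.105 without DMSO 1), FANCC (0.328 without DMSO 1), KCNJ2 (0.227 without Nutlin 2), TCOF1, DHCR24, ACAT2, TM7SF2 (0.429 without DMSO 1), TRIM22, TLR3, IL1A (0.387 without Nutlin 1), CXCL8, ATF3, OAS3 and TGFBI (0.308 without DMSO 2). The call of NUPR1 ended in limma-voom (0.0589), and FANCC was singled out after its values were seen.

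In MCF7, a breast line, the same question was asked. CDKN1A rose from 478 ± 79.0 to 3956 ± 98.2 CPM (3.05 ± 0.35, adjusted p = 5.91e-06) and MDM2 from 65.7 ± 7.65 to 478 ± 12.2 CPM (2.86 ± 0.31, adjusted p = 3.25e-06). BBC3 rose from 46.3 ± 10.9 to 167 ± 9.32 CPM (1.85 ± 0.30, adjusted p = 0.000226), SESN1 by 1.74 ± 0.28 (adjusted p = 0.000211) and GDF15 from 147 ± 102 to 888 ± 354 CPM (2.60 ± 0.44, adjusted p = 0.00068). The G2/M list had a median log2 fold change of −2.61 and the G1/S list one of −1.78. TP53 stood at 259 ± 75.1 CPM with DMSO and 172 ± 65.5 with Nutlin (−0.58 ± 0.31, adjusted p = 0.325).

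In MCF7, 10 of 12 arrest and feedback targets rose (12 adjusted over the list alone, median 1.67, camera adjusted p = 2.35e-16), among them ZMAT3 (2.62 ± 0.30). Of 20 apoptosis targets 14 rose (16 adjusted over the list alone, median 1.46, camera adjusted p = 3.28e-18), with TP53I3 (4.65 ± 0.38, adjusted p = 1.61e-07) and FAS (3.83 ± 0.37) among them. Of 10 DNA repair targets 6 rose and 1 fell (8 and 1 adjusted over the list alone). Camera gave the list an adjusted p of 1.35e-05. Those that rose included GADD45A (2.08 ± 0.32), the nucleotide excision repair gene DDB2 (1.88 ± 0.30) and RRM2B (2.07 ± 0.33), and FANCC (−1.10 ± 0.30) fell. Of 16 metabolism and redox targets 7 rose (7 adjusted over the list alone, camera adjusted p = 5.37e-08), among them the glutaminase gene GLS2 (3.86 ± 0.36) and FDXR (2.99 ± 0.31). Of 20 secreted and surface targets 13 rose (14 adjusted over the list alone, camera adjusted p = 6.36e-14), among them CD82 (2.21 ± 0.29) and INPP5D (5.19 ± 0.63), whose product is intracellular. Of 11 autophagy and lysosome targets DRAM1 (1.21 ± 0.29), ULK1 (1.05 ± 0.29) and ATG4A (0.98 ± 0.28) rose (3 adjusted over the list alone). The list had a camera adjusted p of 0.0237, and the adjusted p was 0.145 with an estimated correlation. The G1/S list had 36 of 41 genes lower (38 adjusted over the list alone, camera adjusted p = 3.32e-44), for example MCM2 (−2.56 ± 0.29) and BRCA1 (−2.48 ± 0.28). The G2/M list had 39 of 40 lower (40 adjusted over the list alone, camera adjusted p = 9.45e-65), among them MKI67 (−3.10 ± 0.30), KIF20A (−3.73 ± 0.35) and HMMR (−3.41 ± 0.35). The 5 p53 lists other than the autophagy list and both cell-cycle lists also passed with an estimated correlation (adjusted p from 0.00285 to 0.0336).

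**Figure D2:**
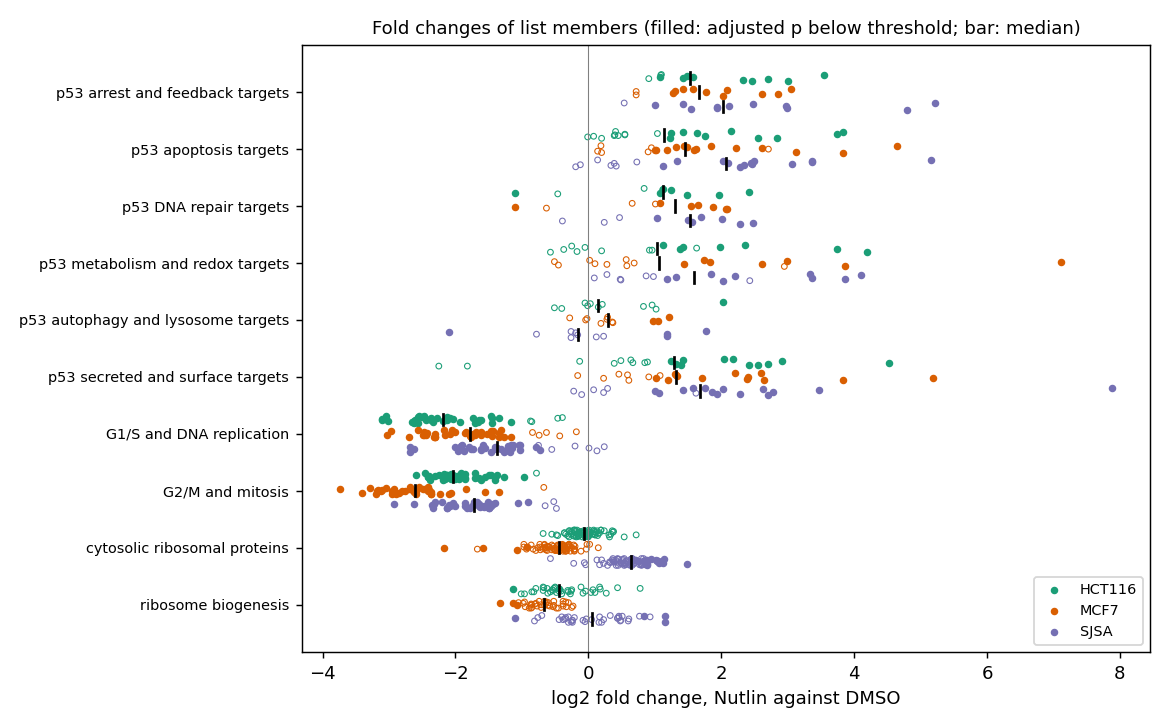
Log2 fold changes of the tested members of 10 gene lists in HCT116, MCF7 and SJSA, with filled circles for genes whose adjusted p passed, open circles for the others and a bar at the median. The G1/S and G2/M lists lay below 0 in each line (medians from −1.38 to −2.61), and the ribosomal protein list had medians of −0.44 in MCF7 and 0.64 in SJSA.

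Ribosomal protein genes had a median of −0.44 in MCF7, with 4 of 79 lower by the test, RPL36A (−2.17 ± 0.52), RPS28 (−1.59 ± 0.42), RPL9 (−0.93 ± 0.27) and RPL14 (−1.07 ± 0.32) (2 adjusted over the list alone, 20 with the batch block). Their camera adjusted p was 1.01e-08, or adjusted p = 0.306 with an estimated correlation. These genes have many processed pseudogenes, so their counts are uncertain. Of 39 ribosome biogenesis genes NOLC1 (−1.33 ± 0.30), FBL (−1.14 ± 0.30) and LYAR (−1.07 ± 0.31) fell (16 adjusted over the list alone, 19 with the block, median −0.66). As a set it had a camera adjusted p of 3.95e-12, and the adjusted p was 0.191 with an estimated correlation. Of 25 integrated stress response genes NUPR1 (3.65 ± 0.44), ATF3 (2.37 ± 0.32), SESN2 (1.44 ± 0.28) and DDIT4 (1.53 ± 0.33) rose (4 adjusted over the list alone). The set test with camera gave an adjusted p of 0.0177, and the adjusted p was 0.357 with an estimated correlation. Of 20 hypoxia and glycolysis genes NDRG1 (2.37 ± 0.30) and BHLHE40 (1.51 ± 0.29) rose (2 adjusted over the list alone, 4 with the block). For the whole list camera gave an adjusted p of 0.00996, and the adjusted p was 0.21 with an estimated correlation. Of 27 interferon response genes TRIM22 (3.43 ± 0.75), IRF9 (1.06 ± 0.30) and DHX58 (56 counts with Nutlin against 3 with DMSO, ratio 12.1, 95% interval 3.94 to 60.6) rose (6 adjusted over the list alone, 9 with the block). The list's adjusted p by camera was 5.52e-05, and the adjusted p was 0.219 with an estimated correlation. Of 19 MAPK and immediate early genes the AP-1 gene FOSL1 (2.27 ± 0.35), the phosphatase gene DUSP4 (1.36 ± 0.29), SPRY4 (1.16 ± 0.33) and PHLDA1 (1.14 ± 0.32) rose (5 adjusted over the list alone, 7 with the block). Camera gave the list an adjusted p of 9.47e-05, and the adjusted p was 0.208 with an estimated correlation. Of the mesenchymal and bone list TGFBI (1.47 ± 0.34) rose (1 of 16, 1 adjusted over the list alone). The list had a camera adjusted p of 0.569. Of 5 nuclear noncoding RNAs the antisense transcript KCNQ1OT1 (−1.50 ± 0.45) fell (2 genes with the block, median 0.08, mean −0.34, camera direction downward, adjusted p = 0.351).

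No member was called in MCF7 by edgeR for 19 other TOP mRNAs (0 at an unadjusted p below 0.05, camera adjusted p = 0.247), 25 sterol synthesis genes (2, 0.503), 17 NF-κB and inflammatory genes (5, 0.0131), 17 estrogen response genes (5, 0.177), 14 epithelial genes (3, 0.351), 11 luminal genes (3, 0.173), 8 intestinal genes (1, 0.649) or 12 snoRNA host genes (2, 0.108). DESeq2 called 2 members of the estrogen list and 1 of the epithelial list, limma-voom called none in these lists, and none passed adjusted over the list alone. The NF-κB list had an adjusted p of 0.235 with an estimated correlation. With 1 library left out, the camera calls of the NF-κB list (0.121 without MCF7 DMSO 1, 0.138 without Nutlin 2), the stress response list (0.107 without DMSO 2, 0.21 without Nutlin 1) and the autophagy list (0.0881 without DMSO 2, 0.0544 without Nutlin 1) ended. The snoRNA hosts then passed (0.0079 without Nutlin 1). With the batch block 4 estrogen response, 3 luminal, 2 epithelial and 2 NF-κB genes were higher and 2 snoRNA hosts and 1 sterol synthesis gene lower.

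In all, 1211 genes passed in MCF7, 630 higher and 581 lower, and 1151 by more than 2-fold (2200 with the batch block, 1205 of the 1211 kept). Fitted alone, MCF7 had 776 genes, and the balance turned to 404 higher and 446 lower without MCF7 DMSO 1 and 328 and 372 without DMSO 2. Several of the 8 largest rises started near 0, with LCE1B (1247 counts with Nutlin against 2 with DMSO, ratio 405, 95% interval 112 to 3350), a cornified envelope gene with near-identical paralogs, NHLH2 (274 counts with Nutlin against 1 with DMSO, ratio 178, 95% interval 31.7 to 7060), DQX1 (422 counts with Nutlin against 3 with DMSO, ratio 91.4, 95% interval 31.1 to 445), HLA-DOA (293 counts with Nutlin against 2 with DMSO, ratio 95.2, 95% interval 26.1 to 790), LCN15 (275 counts with Nutlin against 2 with DMSO, ratio 89.4, 95% interval 24.5 to 742) and TSPEAR (216 counts with Nutlin against 2 with DMSO, ratio 70.2, 95% interval 19.2 to 583). The others were LINC01164 (6.92 ± 0.77) and CYGB (6.35 ± 0.58), which encodes cytoglobin. The 8 largest falls were the meiotic recombinase gene DMC1 (−4.81 ± 0.89), KIF20A, PBK (−3.72 ± 0.35), PIF1 (−3.55 ± 0.45), MNS1 (−3.51 ± 0.56), CDCA3 (−3.43 ± 0.32), HMMR and KIF4A (−3.29 ± 0.33). The count was 700 without MCF7 DMSO 2, 726 without Nutlin 1 and 797 without Nutlin 2. Leaving out at least 1 library ended the calls of DRAM1, ULK1, ATG4A, the 4 ribosomal protein genes (0.217 for RPS28 without MCF7 DMSO 1), NOLC1, FBL, LYAR (0.384 without DMSO 2), DDIT4, TRIM22, DHX58, IRF9, SPRY4, PHLDA1 (0.359 without Nutlin 1), TGFBI, KCNQ1OT1 (0.248 without Nutlin 2) and FANCC (0.345 without DMSO 2). FANCC was singled out after its values were seen.

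In SJSA, an osteosarcoma line with amplified MDM2, the same p53 targets rose. CDKN1A rose from 310 ± 126 to 11486 ± 2977 CPM (5.21 ± 0.39, adjusted p = 1.42e-08) and MDM2 from 2088 ± 7.20 to 16617 ± 3133 CPM (2.99 ± 0.31, adjusted p = 1.26e-06). GDF15 rose from 8.93 ± 4.38 to 2104 ± 125 CPM (7.88 ± 0.57, adjusted p = 2.75e-08), BBC3 from 9.09 ± 2.65 to 323 ± 85.0 CPM (5.15 ± 0.34, adjusted p = 2.86e-09) and SESN1 by 3.33 ± 0.29 (adjusted p = 1.29e-07). Replication and mitosis genes fell, with medians of −1.38 and −1.72. TP53 stood at 199 ± 14.9 CPM with DMSO and 338 ± 43.7 with Nutlin (0.77 ± 0.31, adjusted p = 0.0689) and did not pass. It passed with the batch block (0.0101), with the DESeq2 size factors in edgeR (0.0392), with upper-quartile scaling (0.0406) and in DESeq2 (0.0258). Fold changes in SJSA also rose with the GC content of the transcript (Spearman 0.34 across 16374 genes, against −0.03 in HCT116 and 0.08 in MCF7), from a median log2 fold change of −0.60 in the lowest of 10 GC bins to 0.43 in the highest.

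**Figure D3:**
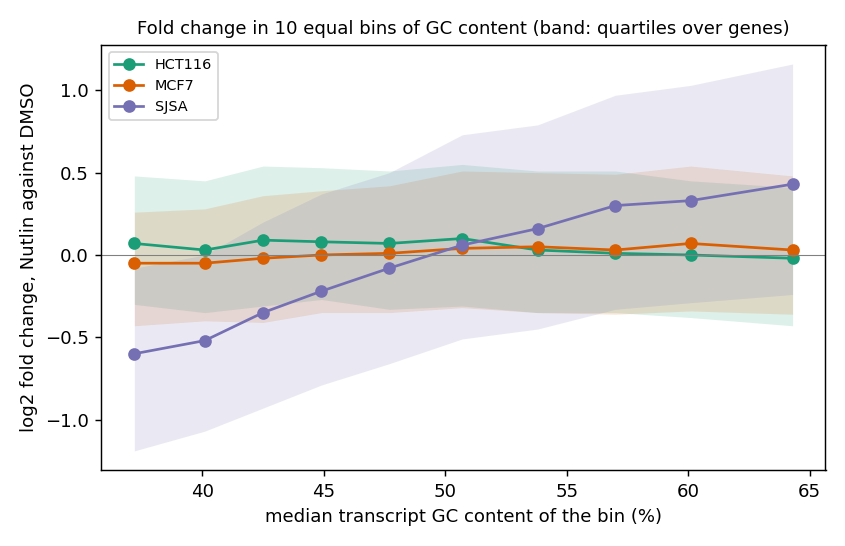
Median log2 fold change of Nutlin against DMSO in 10 equal bins of transcript GC content (percent, x axis), with a band for the quartiles over genes, for HCT116, MCF7 and SJSA. The SJSA median went from −0.60 to 0.43 from the lowest to the highest bin, while the Spearman correlation across genes was −0.03 in HCT116 and 0.08 in MCF7.

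In SJSA, 11 of 12 arrest and feedback targets rose (11 adjusted over the list alone, median 2.03, camera adjusted p = 6.92e-12), among them BTG2 (4.79 ± 0.40). Of 20 apoptosis targets 13 rose (13 adjusted over the list alone, camera adjusted p = 4.4e-10), among them TP53I3 (3.36 ± 0.35) and TP53INP1 (3.36 ± 0.29). With an estimated correlation these lists had adjusted p-values of 0.0121 and 0.0155. Of 10 DNA repair targets 7 rose (7 adjusted over the list alone, median 1.53, camera adjusted p = 6.58e-05), among them GADD45A (2.48 ± 0.33) and RRM2B (2.28 ± 0.34). Of 16 metabolism and redox targets 9 rose (9 adjusted over the list alone, median 1.58, camera adjusted p = 3.52e-08), among them FDXR (4.10 ± 0.33) and SESN2 (3.87 ± 0.31), which restrains mTORC1. Both had adjusted p = 0.0694 with an estimated correlation. Of 20 secreted and surface targets 14 rose (15 adjusted over the list alone, median 1.69, camera adjusted p = 5.71e-09, adjusted p = 0.0856 with an estimated correlation), among them SULF2 (3.47 ± 0.36). Of 11 autophagy and lysosome targets DRAM1 (1.77 ± 0.29), FUCA1 (1.18 ± 0.29) and ULK1 (1.19 ± 0.29) rose and ATG4C (−2.09 ± 0.34) fell (3 and 1 adjusted over the list alone). That list's median was −0.16, its mean 0.07 and its camera direction upward (adjusted p = 0.668). The G1/S list had 35 of 41 genes lower (36 adjusted over the list alone, camera adjusted p = 1.77e-14, adjusted p = 0.205 with an estimated correlation), for example MCM6 (−2.63 ± 0.33) and POLE2 (−2.69 ± 0.35). The G2/M list had 37 of 40 lower (38 adjusted over the list alone, camera adjusted p = 4.57e-20, adjusted p = 0.0769 with an estimated correlation), among them DLGAP5 (−2.93 ± 0.36) and the kinase gene NEK2 (−2.62 ± 0.34).

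Of 25 integrated stress response genes 10 rose and 2 fell in SJSA (10 and 2 adjusted over the list alone, median 0.77). As a set it had a camera adjusted p of 0.00308, and the adjusted p was 0.339 with an estimated correlation. ATF3 (3.91 ± 0.33, adjusted p = 6.83e-08), NUPR1 (5.49 ± 0.50) and DDIT4 (2.99 ± 0.35) rose, and VLDLR (−2.30 ± 0.56) and PCK2 (−1.68 ± 0.33) fell. Of 79 ribosomal protein genes, whose counts pseudogenes make uncertain, 15 rose (0 adjusted over the list alone, 46 with the batch block), for example RPS15 (1.07 ± 0.29), RPL35A (1.02 ± 0.29), RPL38 (1.03 ± 0.30) and RPS19 (1.49 ± 0.45). Their median was 0.64, or 0.65 with the GC trend removed, and their camera adjusted p was 8.78e-07, or adjusted p = 0.469 with an estimated correlation. Of 19 other TOP mRNAs EIF3E (−1.0 ± 0.32) fell (0 adjusted over the list alone, camera adjusted p = 0.668), a call that ended with the GC trend removed (adjusted p = 0.465). Of 39 ribosome biogenesis genes RRP12 (1.15 ± 0.30), NOP16 (1.16 ± 0.35) and EBNA1BP2 (0.84 ± 0.30) rose and POLR1B (−1.11 ± 0.29) fell (2 and 1 adjusted over the list alone, 7 and 4 with the block). The set test with camera gave an adjusted p of 0.626. Of 25 sterol synthesis genes TM7SF2 (1.16 ± 0.35), SREBF2 (0.75 ± 0.26) and PCSK9 (2.38 ± 0.87) rose and ACAT2 (−1.09 ± 0.37) and EBP (−0.99 ± 0.35) fell (0 adjusted over the list alone, 4 and 4 with the block). For the whole list camera gave an adjusted p of 0.874. Of 20 hypoxia and glycolysis genes the angiogenic factor gene VEGFA (2.18 ± 0.29), NDRG1 (1.42 ± 0.29) and PFKFB3 (0.85 ± 0.29) rose and PDK1 (−1.23 ± 0.34), KDM3A (−1.11 ± 0.35) and P4HA1 (−0.98 ± 0.31) fell (3 and 3 adjusted over the list alone). The list's adjusted p by camera was 0.668.

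Of 27 interferon response genes 6 fell and 2 rose in SJSA (9 and 3 adjusted over the list alone, 12 and 3 with the block, median −0.70). Camera gave the list an adjusted p of 0.0225, and the adjusted p was 0.521 with an estimated correlation. IFIT1 (−3.01 ± 0.51), IFI44 (−2.64 ± 0.46) and OAS1 (−2.31 ± 0.62) fell, and TRIM22 (1.91 ± 0.41) and IFI27 (0.98 ± 0.35) rose. Of 17 NF-κB and inflammatory genes IL1B (1.65 ± 0.35), IRF1 (0.97 ± 0.28), NFKB2 (1.01 ± 0.33) and TNFAIP3 (1.05 ± 0.34) rose (4 adjusted over the list alone, 8 with the block). The list had a camera adjusted p of 0.00792, and the adjusted p was 0.314 with an estimated correlation. Of 19 MAPK and immediate early genes 8 rose, including EGR1 (2.49 ± 0.39) and FOSB (2.20 ± 0.43), and ETV4 (−1.27 ± 0.38) fell (8 and 2 adjusted over the list alone). As a set it had a camera adjusted p of 0.00192, and the adjusted p was 0.339 with an estimated correlation. Of 17 estrogen response genes GREB1 (3.24 ± 0.37), RARA (1.81 ± 0.33), CCND1 (1.16 ± 0.31), IGFBP4 (1.0 ± 0.35) and ESR1 (6 counts with Nutlin against 0 with DMSO, at least 2.78-fold higher) rose and PGR (−2.94 ± 0.68) fell (5 and 1 adjusted over the list alone). The set test with camera gave an adjusted p of 0.241. Of 14 epithelial genes 6 rose, among them the tight junction gene CLDN4 (3.27 ± 0.42), the keratin gene KRT8 (1.94 ± 0.36), GRHL2 (29 counts with Nutlin against 3 with DMSO, ratio 13.4, 95% interval 4.16 to 68.8) and the E-cadherin gene CDH1 (2.21 ± 0.63), and SPINT1 (−0.89 ± 0.32) fell (7 and 1 adjusted over the list alone). The GRHL2 rise rested on SJSA Nutlin 1, at 0.73 CPM against 0.04 in Nutlin 2 and 0 and 0.07 in the DMSO libraries. CDH1 was also near 0, at 0.12 and 0.05 CPM with DMSO and 0.6 and 0.18 in Nutlin 1 and 2, so its rise rested mostly on Nutlin 1. CLDN4 went from 0.29 and 0.21 to 1.53 and 3.41 CPM, and KRT8 from 24.5 and 20.8 to 88.2 and 85.7. For the whole epithelial list camera gave an adjusted p of 0.124. Of 16 mesenchymal and bone genes ZEB1 (−2.12 ± 0.39), ZEB2 (−1.37 ± 0.42), CDH2 (−1.08 ± 0.34) and LUM (−1.13 ± 0.39) fell (5 adjusted over the list alone). The list's adjusted p by camera was 0.298. Of 11 luminal genes ESR1, SPDEF (42 counts with Nutlin against 3 with DMSO, ratio 19.4, 95% interval 6.21 to 98), MLPH (1.04 ± 0.35) and KRT19 (1.49 ± 0.44) rose and PGR and FOXA1 (−1.94 ± 0.42) fell (4 and 2 adjusted over the list alone). Camera gave the list an adjusted p of 0.302. Of 8 intestinal genes CDX1 (3.80 ± 0.62) rose (1 adjusted over the list alone). The list had a camera adjusted p of 0.668. Of 12 snoRNA host genes SNHG3 (2.08 ± 0.36) rose (1 adjusted over the list alone, 3 with the block). As a set it had a camera adjusted p of 0.047, and the adjusted p was 0.685 with an estimated correlation. Of 5 nuclear noncoding RNAs KCNQ1OT1 (2.78 ± 0.46) and NEAT1 (1.38 ± 0.50) rose (2 adjusted over the list alone). The set test with camera gave an adjusted p of 0.191. With 1 library left out, the camera calls ended of the NF-κB list (0.0549 without SJSA DMSO 1, 0.0922 without Nutlin 2), the interferon list (0.137 without DMSO 2, 0.0839 without Nutlin 1) and the snoRNA hosts (0.137 without DMSO 2, 0.58 without Nutlin 2, 0.056 without MCF7 DMSO 1 or MCF7 DMSO 2). The epithelial list (0.0153 without DMSO 2, 0.0396 without Nutlin 1) and the sterol list (0.0347 without DMSO 1) passed.

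In all, 4615 genes passed in SJSA, 2122 higher and 2493 lower, and 3872 by more than 2-fold. That balance turned to 2486 higher and 2060 lower with DESeq2 size factors in edgeR, 2404 and 2133 with upper-quartile scaling, 1992 and 1812 with the GC and length trend removed, 2549 and 2272 in DESeq2, 2121 and 1981 fitted alone, and 1367 and 1290 without SJSA Nutlin 2. Of the 8 largest rises TRIM55 (3000 counts with Nutlin against 2 with DMSO, ratio 2080, 95% interval 576 to 17200), UBASH3A (283 counts with Nutlin against 0 with DMSO, at least 131-fold higher), GAS6-AS1 (253 counts with Nutlin against 0 with DMSO, at least 117-fold higher), TSGA10IP (209 counts with Nutlin against 0 with DMSO, at least 96.7-fold higher), TMEM105 (353 counts with Nutlin against 1 with DMSO, ratio 490, 95% interval 87.4 to 19400) and C17orf64 (308 counts with Nutlin against 1 with DMSO, ratio 428, 95% interval 76.2 to 16900) started at 0 to 2 counts, and the others were PVRL4 (9.23 ± 0.63) and PDE6G (8.52 ± 0.75). The 8 largest falls were C3AR1 (−4.69 ± 0.88), E2F5 (−4.02 ± 0.45), C8orf48 (−3.99 ± 0.84), ZNF678 (−3.95 ± 0.55), SALL2 (−3.95 ± 0.52), CNKSR2 (−3.75 ± 0.89), JAKMIP2 (−3.59 ± 0.60) and ARMCX2 (−3.50 ± 0.54). The count was 2791 without SJSA DMSO 2 and 2657 without Nutlin 2. It was 3804 with the GC and length trend removed, a setting chosen after the data were seen, which kept 67.5% of the calls. Testing only the genes with both values, with the trend left in, kept 95.6%. Removing the trend ended the calls of NOP16, TM7SF2, SREBF2, ACAT2, PCSK9, EIF3E, HMMR, KCNJ2, PFKFB3, P4HA1, KDM3A, NFKB2, IGFBP4, ZEB2, CDH2, LUM, KRT19 and MLPH (0.0546 to 0.539). In the other lines it ended those of TGFBI in HCT116 (0.0501) and of LYAR (0.0685), RPL9 (0.0722), SORCS2 (0.057) and ULK1 (0.0532) in MCF7. Leaving out at least 1 library ended the calls of CNKSR2, FUCA1, ULK1, the 4 ribosomal protein genes named, EIF3E, the ribosome biogenesis and sterol genes named, PDK1, KDM3A, OAS1, IRF1, NFKB2, TNFAIP3, PGR, CCND1, GRHL2, CDH1, ZEB2, CDH2, LUM, KRT19, NEAT1, PFKFB3, P4HA1, IFI27, ETV4, IGFBP4, ESR1, SPINT1, MLPH and VLDLR. Examples are NEAT1 without SJSA DMSO 1 (0.265), ACAT2 without DMSO 2 (0.506), ESR1 without Nutlin 1 (1) and IFI27 without Nutlin 2 (0.315). PCSK9, PCK2 and those from PFKFB3 on were singled out after their values were seen.

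The next comparison asked which genes Nutlin changed in every line. In the same direction, 129 genes were higher and 244 lower in all 3 lines, where 1.53 and 2.23 would be shared by independent lists of these sizes. Of the 10 shared rises named, LCE1B, LCE1C, LOC101927501 and LCE1F had the largest fitted means, which depend on the prior count because each of these genes was at 0 to 2 counts under DMSO in at least 1 line. LCE1B, a cornified envelope gene like LCE1C and LCE1F, was at 43.3 times the DMSO level in HCT116 (95% interval 11.7 to 363), 405 times in MCF7 (112 to 3350) and 153 times in SJSA (26.8 to 6090). CLCA2 was at least 9.23-fold higher in HCT116 and rose by 5.0 and 5.97 on the log2 scale in MCF7 and SJSA. The lipid transporter gene ABCA12 rose by 4.93 in HCT116 and 2.61 in MCF7 and was at least 69-fold higher in SJSA, from 0 to 149 counts. FRMPD2 rose by 5.09 on the log2 scale in MCF7, and stood at 33.1 times the DMSO level in HCT116 with a 95% interval of 11 to 163, and 55.5 times in SJSA with one of 9.41 to 2250. The antisense transcript UNC5B-AS1 rose by 3.76, 5.08 and 6.32 on the log2 scale in HCT116, MCF7 and SJSA. ICAM4 and LCE1E, also at 0 to 2 counts under DMSO in at least 1 line, completed the 10. In HCT116 the rises from 0 counts ended at low levels, 0.31 and 0.26 CPM for CLCA2, 0.22 and 0.32 for ICAM4 and 0.5 and 0.16 for LCE1F. The summed level of 376 olfactory receptor genes also rose there, from 26.5 and 40.9 to 84.4 and 87.5 CPM, a smaller ratio than the lower bounds of 9.23, 8.64 and 11 for these 3 genes, which leaves open a part of a higher background in their rises. The 10 shared falls named, NEIL3, DLGAP5, FAM111B, KIF20A, PBK, NEK2, EXO1, NCAPH, WDR76 and the spindle checkpoint gene BUB1, had mean log2 fold changes over the lines between −2.97 and −2.47. NEIL3, a DNA glycosylase gene, fell by 2.41, 4.08 and 2.42 on the log2 scale in HCT116, MCF7 and SJSA. Averaged over the lines, 3760 genes passed, 1821 higher and 1939 lower. The balance turned to 2119 higher and 1661 lower with DESeq2 size factors in edgeR, 2087 and 1679 with upper-quartile scaling, 2338 and 1756 with no filter, and 1841 and 1766 with the GC and length trend removed. Each p53 list except autophagy and both cell-cycle lists passed in that average with either correlation. The number shared by all 3 lines was 593 with the batch block, 241 without HCT116 DMSO 1 and 223 without HCT116 Nutlin 1. At least 1 left-out library ended the HCT116 calls of LCE1C (0.0991 without DMSO 1), LCE1E (0.177), LCE1F (0.175), CLCA2 (0.0524), ICAM4 (0.0777), LOC101927501 (0.157) and FRMPD2 (0.0658 without DMSO 2). It ended the MCF7 calls of LCE1F (0.325 without MCF7 Nutlin 2) and ICAM4 (0.0774 without MCF7 DMSO 2), and the SJSA call of LOC101927501 (0.0758 without SJSA DMSO 2).

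The difference of the Nutlin effect between lines was tested directly, and 1237 genes passed the joint test, 931 of them with the largest absolute log2 fold change in SJSA, 196 in MCF7 and 110 in HCT116. GDF15 (joint adjusted p = 4.49e-05), BBC3 (8.74e-05), CDKN1A (0.0125) and SESN1 (0.0306) rose in every line with the largest value in SJSA. For MDM2 no difference was detected (2.71, 2.86 and 2.99, joint adjusted p = 0.889), and TP53 missed the threshold (joint adjusted p = 0.0773, 0.00918 with the batch block). The smallest p-values belonged to EPS8L2, an actin regulator gene (1.47, 1.34 and 7.26 in HCT116, MCF7 and SJSA), TRIM55, FOXD2-AS1 (−1.25, −1.22 and 3.75). They were followed by HES2 (2.55, 2.71 and 7.70), PVRL4 (4.29, 1.09 and 9.23, the MCF7 value not called at an adjusted p of 0.0842 but called with the block at 0.0164) and the proteoglycan gene CSPG4 (6.12 in SJSA, with −0.05 and 0.53 not called in the others). Among the next, the receptor tyrosine kinase gene AXL rose in MCF7 (4.77) with 0.08 and 0.30 in HCT116 and SJSA, neither called. DHRS2 fell in HCT116 (−1.32) and rose in MCF7 (1.01) and SJSA (3.33). CPNE7, LHX4, TNFSF9 and ARHGAP4 rose in SJSA (4.25, 2.63, 3.88 and 3.63), and in MCF7 CPNE7 and LHX4 fell (−1.23 and −2.0). Several of these folds started near 0. In SJSA, EPS8L2 went from 0.14 and 0.14 CPM with DMSO to 18.9 and 25.4 with Nutlin. HES2 went there from 0.16 and 0.05 to 23.2 and 23.2, and CPNE7 from 0.06 and 0.09 to 1.48 and 1.54. ARHGAP4 started there at 0.14 and 0.23. AXL in MCF7 went from 0.19 and 0.23 to 5.92 and 5.76 CPM, against 582 and 616 in SJSA with DMSO. FOXD2-AS1 and LHX4 started higher in SJSA, at 18.55 and 9.07 and at 8.21 and 4.92 CPM. Between pairs, 43 genes differed between HCT116 and MCF7 (9 with the larger value in HCT116 and 34 in MCF7), 1206 between HCT116 and SJSA (672 and 534) and 1026 between MCF7 and SJSA (506 and 520). These counts depended on the tool and the filter, for HCT116 against MCF7 9 genes with limma-voom, 131 with DESeq2, 178 with no filter and 30 with upper-quartile scaling, and for MCF7 against SJSA 1543 with DESeq2 and 1615 with no filter. The joint test called 2098 genes in DESeq2 and 2175 with no filter. With DESeq2 size factors in edgeR the split of HCT116 against SJSA was 497 and 615, after a shift of the median of −0.104.

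**Figure D4:**
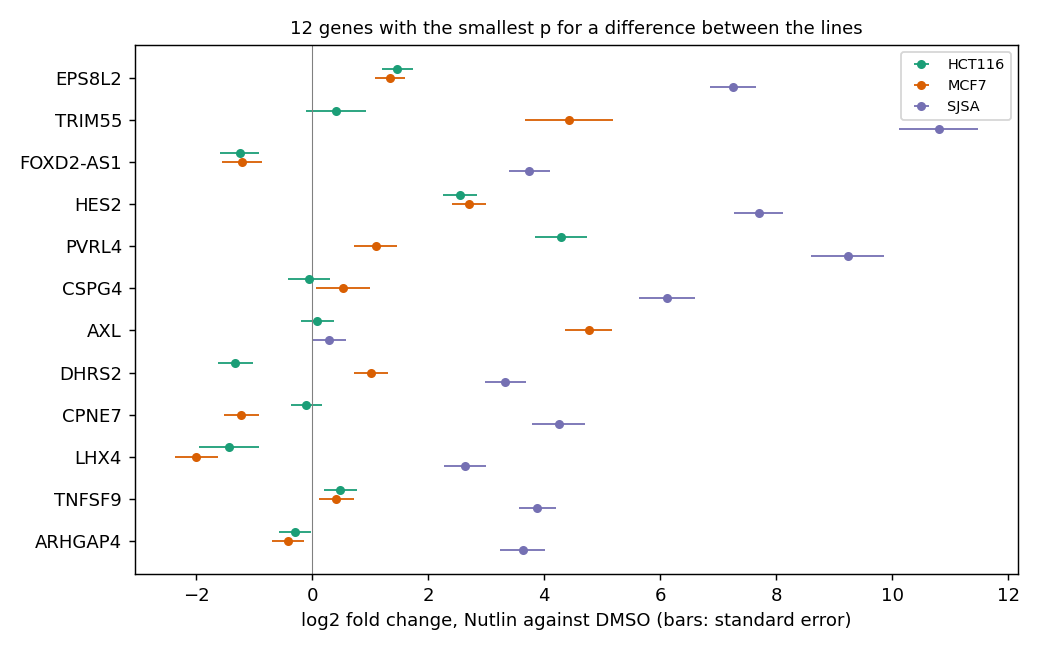
Log2 fold changes of Nutlin against DMSO (x axis, with bars for the SE) of the 12 genes with the smallest p for a difference between HCT116, MCF7 and SJSA. EPS8L2 stood at 1.47, 1.34 and 7.26 in the 3 lines, and the log2 fold change of AXL was highest in MCF7, at 4.77. The 7.26 and the 4.77 started near 0, at 0.14 and 0.14 CPM in SJSA DMSO and 0.19 and 0.23 CPM in MCF7 DMSO.

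With the GC and length trend removed the joint test called 953 genes and kept 807 of the 1237 (65.2%), and the split of HCT116 against SJSA was 388 and 423. Testing only the genes with both values, with the trend left in, kept 1192 of the 1237 (96.4%). The joint count was 3293 with the batch block, 650 without SJSA Nutlin 1 and 537 without SJSA Nutlin 2. With the block the pairs had 160, 3052 and 2589 genes. HCT116 against MCF7 fell to between 18 and 26 without HCT116 DMSO 1 (21), HCT116 Nutlin 1 (18), HCT116 Nutlin 2 (24) or MCF7 DMSO 1 (26). HCT116 against SJSA fell to between 591 and 694 without HCT116 DMSO 1 (591), HCT116 DMSO 2 (671), HCT116 Nutlin 1 (624), HCT116 Nutlin 2 (663), SJSA Nutlin 1 (694) or SJSA Nutlin 2 (605). MCF7 against SJSA fell to between 455 and 682 without MCF7 DMSO 2 (612), MCF7 Nutlin 1 (637), SJSA DMSO 2 (682) or SJSA Nutlin 2 (455). The joint call of CDKN1A ended without SJSA Nutlin 1 (0.0772) or SJSA DMSO 2 (0.0615) and that of SESN1 without SJSA Nutlin 1 (0.108), while the joint calls of the 12 genes with the smallest p, of BBC3 and of GDF15 passed in all 12 fits with 1 library left out. The calls within a line ended for FOXD2-AS1 (0.312 without HCT116 Nutlin 2, 0.182 without MCF7 Nutlin 2), DHRS2 (0.16 without HCT116 DMSO 1, 0.319 without MCF7 DMSO 1) and CPNE7 (0.184 without MCF7 Nutlin 2). Fold changes in SJSA moved with GC content (Spearman 0.34), and antisense genes such as FOXD2-AS1 are uncertain because the strand setting of the counting was not given in the sources used here.

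Under DMSO the lines were compared for the p53 lists, for MDM2, for TP53 and for the identity lists. MDM2 was lower in HCT116 than in SJSA (log2 difference −4.67 ± 0.34, adjusted p = 1.43e-10) and lower in MCF7 than in SJSA (−4.99 ± 0.34, adjusted p = 5.27e-11), and HCT116 and MCF7 did not differ by the test (0.32, adjusted p = 0.384). TP53 was lower in HCT116 than in MCF7 (−1.34, adjusted p = 0.00125) and than in SJSA (−0.96, adjusted p = 0.0131), with 0.38 between MCF7 and SJSA (adjusted p = 0.305). Differences under DMSO were common among all 17005 tested genes, with 48% called between HCT116 and MCF7, 49.7% between HCT116 and SJSA and 55.7% between MCF7 and SJSA. The p53 lists held 12, 20, 10, 16, 11 and 20 tested genes, with some genes in more than 1 list. Each gene counted once, 53 p53 list genes differed between HCT116 and MCF7, 51 between HCT116 and SJSA and 56 between MCF7 and SJSA. In each pair this was a larger share than over all tested genes, an excess that was not tested. The differences went both ways, for example 8 of 20 secreted and surface targets higher and 9 lower in HCT116 than in MCF7 (9 and 10 adjusted over the list alone). No p53 list as a whole passed (camera adjusted p from 0.133 to 0.986). All 11 luminal genes and 16 of 17 estrogen response genes were lower in HCT116 than in MCF7 (camera adjusted p = 2.72e-09 and 1.79e-11). All 14 epithelial genes were higher in HCT116 and in MCF7 than in SJSA (1.25e-13 and 2.14e-13), and 15 of 16 mesenchymal and bone genes were lower (9.66e-13 and 1.72e-10). Adjusted over the list alone these identity counts were 11, 16, 14, 14, 15 and 15 in the same order. With an estimated correlation the calls of the luminal list (0.135), of the epithelial list between HCT116 and SJSA (0.0526) and of the mesenchymal and bone list in both comparisons (0.0526 and 0.0561) ended. Those of the estrogen list (0.0287) and of the epithelial list between MCF7 and SJSA (0.0469) passed. Line and any difference in how the lines were handled cannot be told apart in these contrasts.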

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

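The tests of why SJSA had more called genes, the test of GC bias for its epithelial and luminal genes and the count of other splits were chosen only after the result was seen, and the tests of the GC trend and of foreign RNA or DNA in SJSA were written before. Each gene and list below drew attention because its Nutlin effect differed between the lines by a test of the difference itself. The joint test called 1237 genes, and the pairs 43 for HCT116 against MCF7, 1206 for HCT116 against SJSA and 1026 for MCF7 against SJSA.

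Of the p53 targets named, the joint adjusted p was 0.0125 for CDKN1A, 8.74e-05 for BBC3, 4.49e-05 for GDF15, 0.0306 for SESN1, 0.00427 for BTG2, 0.00976 for FDXR, 0.00747 for SULF2 and 0.000219 for SESN2. Of cell-cycle genes it was 0.0497 for CCNE2, 0.0238 for MCM2, 0.0297 for KIF20A, 0.0206 for PBK, 0.0253 for PIF1, 0.0252 for CDCA3, 0.0322 for HMMR, 0.0241 for KIF4A and 0.000219 for E2F5. Of genes of translation and ribosome synthesis it was 0.0218 for RPS28, 0.0367 for RPL9, 0.035 for RPL14, 0.0264 for RPS15, 0.0189 for RPL38, 0.0421 for LYAR and 0.0499 for NOP16. Of stress and hypoxia genes it was 0.00411 for ATF3, 0.00976 for DDIT4, 0.0123 for NDRG1 and 0.00335 for VEGFA. It was 0.012 for the autophagy gene ATG4C and 0.0205 for the sterol synthesis list gene INSIG1. Of interferon, inflammatory and immediate early genes it was 0.0379 for OAS3, 0.0367 for OAS1, 0.0244 for DHX58, 0.0216 for IRF9, 0.00174 for IFIT1, 0.011 for IFI44, 0.00993 for ICAM1, 0.00854 for FOSL1 and 0.000794 for EGR1. Of identity genes it was 0.000958 for GREB1, 0.0267 for RARA, 0.0421 for IGFBP4, 0.00464 for CLDN4, 0.00399 for KRT8, 0.00809 for ZEB1, 0.000927 for SPDEF, 0.00957 for FOXA1, 0.000789 for COL5A1 and 0.00588 for TGFBI.

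Of the largest changes within lines, the joint adjusted p was 0.00227 for ABCA12, 0.00269 for SORCS2, 0.00105 for CBS, 4.14e-06 for PVRL4, 0.0132 for DQX1, 0.00315 for HLA-DOA, 0.000129 for CYGB, 3.06e-06 for TRIM55, 0.00485 for GAS6-AS1, 0.0028 for TSGA10IP, 0.000163 for TMEM105, 0.00163 for PDE6G, 0.046 for C17orf64, 0.0412 for C8orf48, 0.00163 for ZNF678, 0.00585 for SALL2 and 0.0226 for JAKMIP2. Of noncoding RNAs it was 0.000499 for KCNQ1OT1, 0.00206 for SNHG3, 0.0351 for UNC5B-AS1 and 3.06e-06 for FOXD2-AS1. It was 2.81e-07 for EPS8L2, 4.14e-06 for HES2 and CSPG4, 1.23e-05 for AXL, DHRS2 and CPNE7, 3.3e-05 for LHX4, 3.54e-05 for TNFSF9 and 4.49e-05 for ARHGAP4. Some joint calls ended with a library left out. Without SJSA Nutlin 2 these were ATG4C (0.0773), CLDN4 (0.0513), DDIT4 (0.0689), FOXA1 (0.062), LYAR (0.139), NOP16 (0.168), RPL14 (0.159), RPL38 (0.107), RPS15 (0.161), RPS28 (0.103) and ZEB1 (0.0564). Without SJSA Nutlin 1 they were CDKN1A (0.0772), HMMR (0.086), MCM2 (0.109), OAS1 (0.168) and SESN1 (0.108). Without SJSA DMSO 2 they were IFI44 (0.0706), JAKMIP2 (0.11) and RARA (0.11). Without MCF7 DMSO 2 they were C17orf64 (0.376), CDCA3 (0.0974), IRF9 (0.0755) and KIF20A (0.105). Without MCF7 Nutlin 1 they were KIF4A (0.077), PBK (0.088), PIF1 (0.109) and RPL9 (0.167). Without MCF7 Nutlin 2 they were C8orf48 (0.265), CCNE2 (0.251) and OAS3 (0.135). Others were DHX58 (0.109 without MCF7 DMSO 1), DQX1 (0.14 without HCT116 DMSO 2), UNC5B-AS1 (0.129 without HCT116 DMSO 2), ICAM1 (0.081) and IGFBP4 (0.831), both without HCT116 DMSO 1, and INSIG1 (0.0956 without HCT116 Nutlin 2). For some of these, other libraries also ended the call, and the value is the highest. Removing the GC and length trend, a setting chosen after the data were seen, ended the joint calls of NOP16 (0.121), ATG4C (0.0933), UNC5B-AS1 (0.076), C17orf64 (0.072), IGFBP4 (0.072), RPS15 (0.0711), C8orf48 (0.0648), OAS1 (0.0648), RPS28 (0.0644), JAKMIP2 (0.0629), RARA (0.0614), MCM2 (0.0557) and CCNE2 (0.0532). With the block as well, C17orf64 (0.0632) and C8orf48 (0.0653) stayed above the threshold. With the batch block alone no joint call of a named gene ended, and ARMCX2, ATG4A, BHLHE40, CDH1, CLSPN, DHCR24, DTL, DUSP5, EBNA1BP2, ETV4, FAS, FOSB, GRHL2, IL1A, INPP5D, IRF1, KDM3A, KIF2C, KRT19, MKI67, MNS1, MYB, NFKB2, NUPR1, PCK2, PCSK9, PDK1, PGR, POLR1B, RPL35A, RPL36A, RPS19, RRP12, SPINT1, SREBF2, TP53, TP53I3, TP53INP1, VLDLR and ZNF367 passed as well (0.0032 to 0.0496).

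Between pairs of lines 32 list differences passed camera with the preset correlation, and none of them held with an estimated correlation or by fry. For HCT116 against MCF7 the adjusted p was 0.0292 for p53 apoptosis targets, 0.0161 for G1/S, 8.32e-09 for G2/M, 5.74e-06 for ribosomal proteins, 0.0053 for ribosome biogenesis, 0.000125 for sterol synthesis, 0.00147 for stress response, 1.62e-06 for hypoxia, 1.16e-05 for interferon, 0.000209 for MAPK, 0.0292 for estrogen response, 0.00817 for epithelial, 0.00901 for luminal and 1.29e-05 for snoRNA host genes. For HCT116 against SJSA it was 0.0491 for p53 arrest targets, 0.0182 for p53 metabolism targets, 7.88e-06 for G1/S, 2.05e-06 for ribosomal proteins, 0.00442 for ribosome biogenesis, 0.00819 for sterol synthesis, 0.000261 for stress response, 0.0105 for MAPK and 0.00819 for epithelial genes. For MCF7 against SJSA it was 0.0352 for p53 arrest targets, 0.0135 for p53 metabolism targets, 0.00407 for G1/S, 2.17e-08 for G2/M, 3.65e-16 for ribosomal proteins (median difference −1.12, 13 members lower in MCF7), 4.24e-07 for ribosome biogenesis, 0.0437 for stress response, 2.34e-06 for interferon (median difference 1.52, 8 members higher in MCF7) and 0.00516 for snoRNA host genes. With an estimated correlation the adjusted p lay between 0.242 and 0.754 for the first pair, 0.477 and 0.502 for the second and 0.421 and 0.635 for MCF7 against SJSA.

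Nutlin called 4615 genes in SJSA, 3.81 times the larger count of the other lines. GC and length bias as the whole cause is argued against by a ratio of 3.06 with that trend removed, and 2.39 with the block as well. Depth is argued against by a ratio of 3.74 with every library thinned, and a spread shared by the lines by a ratio of 2.14 with each line fitted alone. A stronger response of SJSA, whose MDM2 level under DMSO was also the highest, stays open as a hypothesis that was not tested, and other differences between the lines could play a part.

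Fold changes in SJSA rose with GC content (Spearman 0.34). Genes with few counts do not account for it, since the correlation was 0.38 among 8710 genes with at least 10 CPM. GC bias that varies from library to library may be the source and stays open, because the largest replicate difference in the GC contrast (0.32, in MCF7 DMSO) was 0.515 times the smaller Nutlin effect of the SJSA batches, just over the bound of 0.5. The contrast was 0.62 in batch 1 and 1.06 in batch 2 of SJSA. An effect of Nutlin on GC-rich transcripts in SJSA stays open too.

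Of the epithelial and luminal lists in SJSA 6 of 14 and 4 of 11 genes rose and 1 and 2 fell, and neither list passed camera (adjusted p = 0.124 and 0.302), so the tests here bear on the 9 members that rose. RNA from MCF7 cells would have to make up 0.222% by their median, while 32 genes abundant in MCF7 and near 0 in SJSA, such as TFF1 and S100A14, showed a median of 0.00775%, a ratio of 0.0349. The highest of the 32 showed 1.55%, more than the share needed. RNA from HCT116 cells would need 2.2%, and 10 genes abundant in HCT116 and near 0 in SJSA showed a median of 0.00932% (highest 0.331%), a ratio of 0.00424. Genomic DNA is argued against by a ratio of 0.00832 for the rise of 376 olfactory receptor genes. GC and length bias as the whole cause is argued against by a median share of 0.956 of their log2 fold changes left with that trend removed (lower quartile 0.921), though the calls of KRT19 (1.49 ± 0.44 before and 1.0 ± 0.46 after, adjusted p = 0.122) and MLPH (1.04 ± 0.35 and 0.96 ± 0.36, 0.063) ended, the first with a smaller fold and the second just past the threshold. SJSA medians ran only from −0.60 to 0.43 across GC bins, so that trend could take up little of the larger rises in any case. The values above argue against each of these sources as the main source for the 9 genes as a set but do not exclude them for single genes. The GRHL2 rise rested on SJSA Nutlin 1 (0.73 CPM against 0.04 in Nutlin 2), and ESR1 had 6 counts with Nutlin against 0 with DMSO. CDH1 (0.6 and 0.18 CPM) and CLDN4 (1.53 and 3.41 CPM) also stayed at low levels in the SJSA Nutlin libraries. A rise within SJSA cells stays open as a hypothesis found in these data.

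The average over the lines called 3760 genes, and 1 of 100 splits of the libraries within lines, the real one, gave as many. A share of 1 in 100 is the smallest these splits could give, so it argues against a chance division of the libraries without excluding it. In the other splits the treatment effect stays within groups or cancels between lines, which lowers their counts. The splits also cannot show whether replicates were independent. The highest other split gave 1504 genes and parted 6 pairs, as the real one did, with 4 libraries moved. The splits by batch gave at most 0.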

How the results depend on the processing

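The GC and length settings were chosen after the data were seen, and the others before. Of the values of named genes, 7065 kept their direction and side of the threshold, 292 lost the call and 13 gained it, and 6 that were never called changed sign. Of the list values 1086 kept both, 54 lost the call, 12 gained it and 19 that were never called changed sign. No called value reversed. Most named genes were chosen because they were called, by fold or by p, so few could gain a call or reverse. Of the 7065 gene values kept, 3468 came from fits with a library left out. In most of those fits the library belonged to another line than the value. The gene tally therefore does not show how stable the calls of other genes are. Where a count below moved, the cause was not tested. A left-out library and a fit of the compared lines alone also use fewer samples, which does not account for the rise from 778 to 1920 genes in HCT116 fitted alone.

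The replicate block moved the counts to 1791 in HCT116, 2200 in MCF7, 593 in all 3 lines, 3293 for the joint interaction, and 160, 3052 and 2589 for HCT116 against MCF7, HCT116 against SJSA and MCF7 against SJSA. It kept at least 99.4% of the calls in each line, on average and in the joint test, the contrasts for which kept calls were counted. It ended no call of a named gene within a line or in the joint test, and it added calls of named genes in every line, such as EBP in HCT116 (0.0013) and MCF7 (0.00615) and RPL14 in SJSA (0.00887). With the GC and length trend removed and the replicate block, the counts were 2128 in HCT116, 2486 in MCF7, 658 in all 3 lines, 3079 for the joint interaction, and 211, 2804 and 2399 for the pairs in that order. No filter gave 1170 in HCT116, 2175 for the joint interaction, 178 for HCT116 against MCF7 and 1615 for MCF7 against SJSA. DESeq2 gave 2098 for the joint interaction, 131 for HCT116 against MCF7 and 1543 for MCF7 against SJSA, and limma-voom 9 for HCT116 against MCF7. The lines fitted alone gave 1920 in HCT116 and 776 in MCF7. Among the settings on all 12 libraries or on lines fitted alone, the balance of higher against lower calls also turned on average in DESeq2 (2315 and 1823) and limma-voom (1993 and 1953), for HCT116 against SJSA with DESeq2 size factors in edgeR (497 and 615), in DESeq2 (843 and 956) and limma-voom (571 and 623), and for MCF7 against SJSA with no filter (931 and 684) and the replicate block (1375 and 1214). With the GC and length trend removed and the block it turned in SJSA (3135 and 2804), on average (2816 and 2653) and for HCT116 against SJSA (1318 and 1486). Leaving out 1 library turned it in each line, on average (1659 and 1579 without HCT116 Nutlin 2, 1745 and 1617 without MCF7 Nutlin 2) and for both comparisons with SJSA, as in MCF7 without DMSO 1 (404 and 446) and in SJSA without Nutlin 2 (1367 and 1290).

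Leaving out each library in turn gave 333 to 979 genes in HCT116, 700 to 1371 in MCF7, 2657 to 4793 in SJSA, 223 to 390 in all 3 lines, 2822 to 4352 on average, 537 to 1282 for the joint interaction, 18 to 61, 591 to 1320 and 455 to 1103 for the pairs, and 38 to 53, 39 to 53 and 48 to 58 p53 list genes under DMSO for HCT116 against MCF7, HCT116 against SJSA and MCF7 against SJSA. The lowest of the first counts came without HCT116 Nutlin 1, MCF7 DMSO 2 and SJSA Nutlin 2.

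Fry ended the calls, at the adjusted p given, of the HCT116 ribosome biogenesis (0.21), sterol (0.21), hypoxia (0.21) and snoRNA host (0.357) lists, of the MCF7 ribosomal protein (0.0871), stress response (0.0871) and NF-κB (0.0511) lists and of the SJSA ribosomal protein (0.0516), interferon (0.0576) and snoRNA host (0.305) lists. It added HCT116 autophagy (0.00696) and SJSA noncoding RNAs (0.0333). DESeq2 size factors ended the SJSA snoRNA hosts (0.0511). The mitochondrial setting was not run because the table names no such gene. Thinning to the smallest library moved no count by over 1.5 times. Depth limits folds from near 0 counts, whose intervals are wide.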

Other observations

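The test of the chromosome 12 genes was chosen only after the result was seen, and all genes named here were chosen after their values were seen. Some genes were called in opposite directions in different lines, 13 between HCT116 and SJSA, 32 between MCF7 and SJSA and 3 between HCT116 and MCF7, the last being DHRS2, KRT6A and TGFBI. CBS, which encodes cystathionine beta-synthase, rose in HCT116 (4.30) and fell in SJSA (−1.21, joint adjusted p = 0.00105). In HCT116 it was near 0, at 0.07 and 0.12 CPM with DMSO and 3.07 and 0.68 with Nutlin. In SJSA it went from 140 and 187 to 64.9 and 76.0 CPM. SYTL1, which encodes a Rab27-binding protein, rose in HCT116 (2.25) and MCF7 (1.83) and fell in SJSA (−1.40, joint adjusted p = 0.000122), and RAB27B rose in MCF7 (1.18) and fell in SJSA (−2.46, joint adjusted p = 9.78e-05). NDRG4 rose in HCT116 (1.31) and fell in SJSA (−2.23, joint adjusted p = 0.000137). The snoRNA host gene SNHG10 fell in MCF7 (−1.47) and rose in SJSA (2.97, joint adjusted p = 0.000412).

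In HCT116 the summed level of 376 olfactory receptor genes was 26.5 and 40.9 CPM in the DMSO libraries and 84.4 and 87.5 CPM in the Nutlin libraries. In SJSA it was 1.66 and 1.97 CPM with DMSO and 5.09 and 4.76 with Nutlin, and in MCF7 between 0.953 and 1.59 in all 4 libraries. The SJSA sums entered only the test for genomic DNA, and those of HCT116 and MCF7 were not tested.

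A run of 25 neighbouring genes on chromosome 12, from GLI1 to XRCC6BP1, was high in SJSA under DMSO, with a median log2 ratio of 3.15 over the higher of the other lines, where the highest of 15917 other runs of as many genes reached 1.35. GLI1 stood at 726 CPM in SJSA against 3.35 in HCT116 and 0.698 in MCF7, CDK4 at 4740 against 573 and 581, and OS9 at 9750 against 122 and 294. The hypothesis that the run falls together with Nutlin was not borne out. Its median SJSA log2 fold change was −0.12, at percentile 44 of runs of as many genes, with 8 of its genes called lower and 3 higher.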
